A study of Mus musculus with 2 samples.

How the data were processed

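Single-cell RNA-seq libraries were made with the 10x Genomics Chromium 3' chemistry (v2), per the labels' protocols, from CD8 T cells sorted out of mouse tumours. The labels list 2 samples, 1 for T cells transduced with a lentiviral guide RNA against Dhx37 and 1 for T cells transduced with the vector alone, so each group is 1 library. Cell Ranger 1.3 and the mm10 genome build are named per the submitters' processing notes. The deposited values are raw UMI counts per gene and cell barcode, with 27998 genes and 601 barcodes in 1 table. All values were whole numbers, and totals per barcode differed, as in counts that have not been normalised. The filter by which barcodes were kept, and whether the depths of the libraries were equalised when they were joined, are not given in the sources used here.

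The barcodes carry 2 suffixes, with 225 cells of one (barcode set 1) and 376 of the other (barcode set 2). No label ties a suffix to a sample. A suffix was not assigned to a treatment by its number, its order or the level of any gene. All cells were therefore treated as 1 pooled sample, and no comparison of the guide RNA with the vector was made. Planned ratios between the groups, by gene and by gene list, were not computed. Values for each barcode set are given as values of unassigned libraries.

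Levels are given as CPM, the UMIs of a gene or list per 1000000 UMIs of the cells concerned. Sums of UMIs have exact Poisson 95% intervals, shares of cells exact (Clopper-Pearson) binomial 95% intervals, and ratios of CPM the exact conditional binomial 95% interval. These intervals cover counting error only. Cells are not replicates, so no p-value, standard error or number of changed genes was made from them. Where a gene was absent from the other cells, its fold was set against 3 counts over those cells and is a lower bound. A count of 0 cells allows up to 3 cells.

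Cells were clustered with scanpy 1.11.5 (Leiden, resolution 0.8, 15 neighbours, 20 principal components of the 1500 most variable genes, log of counts per 10000). The median depth was 5007 UMIs and 1728 genes per cell. No cell was removed in the main setting. Doublets were predicted with scrublet in scanpy at an expected rate of 0.05, separately for each barcode set, and 23 cells were marked; they were kept in the main setting and removed in an alternative. A cell passed the T cell rule with at least 1 UMI of Cd3d, Cd3e, Cd3g, Cd8a or Cd8b1 and under 3 UMIs over the macrophage or monocyte, B cell and tumour epithelial marker lists. To compare shares of cells with a UMI, each cell was thinned to 2000 UMIs, which kept 515 cells (182 of 225 in barcode set 1 and 333 of 376 in barcode set 2); shallower cells were left out. The other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9.

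The 17 marker lists, the 19 gene lists, the thinning rule, the clustering settings and the rule for named genes were fixed before the data were examined. That rule names the 5 genes of highest fold in each cluster with at least 50 UMIs, members of the marker lists with at least 50 UMIs, and 19 genes chosen for shares of cells. Genes outside it are marked where they appear. Trac, Trbc1, Trbc2 and Ighm matched no row by symbol and were not used here.

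The rule that gives a cluster its name was not fixed in advance. It was set after the clusters had been seen, and 4 versions were tried. All versions asked for at least 3 markers of a list at 2-fold or higher, a median of at least 3 UMIs of the list per cell, and no other list with more markers among the leading genes. The first version asked for no marker of the list itself among the leading genes, and it named cluster 3 exhausted-like and cluster 9 macrophage-like although other genes led them. The second, which was kept, asked for at least 1 among the 10 genes of highest fold. The third asked for 1 among the leading 20 and again named cluster 9. The fourth called a macrophage-like cluster by its level (a median of at least 20 UMIs of the list and no T cell gene UMI) and was written because the kept rule lost that name under 5 of 9 alternatives; it was withdrawn because its limit had been picked for 1 class from the values seen. The second was kept because a cluster led by genes that go against its name should have none. Clusters 3 and 9, which this choice leaves unnamed, hold 12.8% and 3.33% of the cells. The names under each version, and the values that rest on them, are given with the alternatives.

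After it was seen that no barcode could be mapped to a sample, a further comparison was added among thinned cells that had passed the T cell rule before thinning (342 cells): cells with a UMI of Pdcd1, Ifng or Tcf7 against cells without one. The 3 genes and this comparison were chosen after the table was seen. All 19 lists were computed for each gene, 57 pairs in all, and 11 pairs were followed through the alternatives after their values had been seen. A list member counts as higher or lower at a ratio of 1.5, with 0.5 added to each sum. Because a second thinning draw moved some ratios beyond their intervals, 50 draws were then made, and the median, lowest and highest ratio over the draws are given. These draws cover all T cells together, so ratios within a barcode set come from the first draw alone and their spread over draws is unknown. In that draw 46, 25 and 28 cells of barcode set 1 had a UMI of Pdcd1, Tcf7 and Ifng, and 45, 43 and 61 of barcode set 2. The gene that splits the cells is left out of its lists.

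Cluster folds and the split by a gene were tested on simulated counts. In 55 of 601 simulated cells, 100 genes raised 2-fold gave a median fold of 1.86 against a target of 1.92, and 96.0% of the intervals held the target. For 100 genes raised 4-fold the median was 3.81 against 3.84, with 96.0% of the intervals holding it. Of 6490 unchanged genes, 1.19% had an interval above 1. For the split by Ifng in simulated cells of 1 profile, 96.2% of the intervals of 2902 genes held 1. Real cells differ in state, so which cells are sampled adds error that these intervals leave out.

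Gene positions are from GENCODE M21 on GRCm38 (the assembly that mm10 names); 27645 of 27998 identifiers matched it. Alternatives covered the clustering resolution, the number of components, clustering without cell cycle and ribosomal protein genes, filters on genes per cell and mitochondrial share, doublets, the deepest cells, the total used for scaling, thinning, each barcode set alone and the naming rule.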

Results

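The data are single-cell transcriptomes of CD8 T cells taken from E0771-mCherry-OVA tumours, a mouse mammary tumour line made to express ovalbumin. The T cells came from OT-1 mice, whose T cell receptor recognises an ovalbumin peptide, that also carry the Cas9 nuclease. They were given a lentivirus with a guide RNA against Dhx37, or the vector alone, and transferred into tumour-bearing mice without T and B cells of their own (Rag-/-). The study asked how targeting Dhx37 changes infiltrating CD8 T cells. The 2 libraries, 1 per group, were in 1 table of cells (225 in barcode set 1, 376 in barcode set 2) whose barcodes name no sample, so the groups could not be compared and the cells are described as 1 pool. The pool held 3633248 UMIs, 1263977 in barcode set 1 and 2369271 in barcode set 2. Cells held 827 to 82508 UMIs. There are no replicates, and every interval below covers counting error only.

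Dhx37, a DEAH-box RNA helicase, was sparsely detected. The gene (ENSMUSG00000029480) lies on chromosome 5 at 125413858 to 125434121 on the minus strand and is protein coding. It had 21 UMIs in the pool, a level of 5.78 CPM (95% interval 3.58 to 8.84). A UMI was found in 3.33% of cells, and in 3.41% of macrophage-like cells, which were not the target of the guide RNA. Cas9 makes small insertions and deletions that need not lower a transcript counted at its 3' end, so the level does not check the labels.

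T cells made up most of the pool, and cells of other types were present in the sort. The T cell rule was passed by 382 cells (63.6%, 59.6 to 67.4). This share rose to 85.5% with no limit on the other lists, so it depends on how UMIs of other types are read. It was 78.1% after thinning, which both lowers the UMIs per cell and leaves out 86 shallower cells. Markers of macrophages or monocytes summed to 4333 CPM, and 34.4% of cells had at least 3 UMIs of them. Dendritic cell markers, mainly MHC class II genes that macrophages also express, summed to 1535 CPM, with 66 cells at 3 UMIs or more. The NK cell list reached 387 CPM and 22.6% of cells, and it shares Tyrobp with the macrophage list. Only 3 of its 7 genes had at least 50 UMIs. Among cells passing the T cell rule the list stood at 164 CPM, with 9.42% of these cells at 3 UMIs or more. It therefore does not by itself mark NK cells. Fibroblast markers summed to 90.8 CPM with 12 cells at this level, and tumour epithelial markers to 50.4 CPM with 10. Endothelial (25 CPM), CD4 T cell (24.5 CPM), erythroid (5.78 CPM), B cell (5.23 CPM) and neutrophil (4.13 CPM) lists were low. Mast cell or basophil markers had 0 UMIs.

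The T cells separated into states that differed in inhibitory receptors, cytotoxic genes, interferon response, memory genes and division. These genes describe the clusters and are not tests of them. Each fold sets a cluster against all other cells of the pool, cells of other types included. A T cell gene at a fold near 2 may thus partly mark T cells in general. An exhausted-like cluster of 55 cells (9.15%, 6.97 to 11.7) had all 7 measured exhaustion markers at 2-fold or higher; it held 22.7% of barcode set 1 and 1.06% of barcode set 2. Tox, a transcription factor of exhausted T cells, stood at 338 CPM against 30.6 in the other cells (11.1-fold, 8.31 to 14.7), and Havcr2, which encodes the inhibitory receptor TIM-3, at 221 against 21.9 CPM (10.1-fold, 7.12 to 14.3). Pdcd1, which encodes PD-1, was at 613 CPM (5.58-fold, 4.65 to 6.68) and Lag3 at 519 CPM (5.99-fold, 4.89 to 7.30). Of 18 measured cytotoxic effector genes, 9 were 2-fold or more higher in these cells and 2 were 2-fold or more lower; Gzmb was at 2468 CPM (4.09-fold) and Prf1 at 93.7 CPM (4.40-fold). Their leading genes were Cd7, Tox, Ccl3, Havcr2 and Ccl4. Il7r, the receptor of the survival cytokine IL-7, had 2 UMIs in this cluster. Its share was larger in some settings, with 132 cells at resolution 0.4 and 18.4% after the gene and mitochondrial filters.

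The other T cell states were marked by different genes. An interferon-responding-like cluster of 65 cells (10.8%, 8.45 to 13.6) had all 9 marker genes and all 29 measured interferon-stimulated genes at 2-fold or higher. Ifit3 was at 1357 against 152 CPM (8.94-fold, 7.84 to 10.2), Isg15 at 744 CPM (5.03-fold) and Gzmb at 1712 CPM (2.58-fold); Gbp2b, Cxcl10, Tgtp1, Ifit3b and Trim30c led it. Its share was 21.6% in thinned cells. A memory or naive-like cluster of 59 cells (9.82%, 7.56 to 12.5) had 4 of 7 markers at 2-fold or higher, with Lef1, a transcription factor of naive T cells, 3.02-fold (1.76 to 4.95), S1pr1 2.12-fold and Il7r 2.06-fold higher. Lcn4, Gzma, Rasgrp2 and Fam78a were among its leading genes, but the Gzma UMIs came from 2 cells, the cluster's share ran to 41.3% at resolution 0.4, and the name was not reached under 4 of 9 alternatives. Its marker list stood at 2551 CPM, close to the 2493 CPM of the unnamed cluster 1. S1pr1 had a higher fold in the unnamed cluster 4 (2.65-fold, 1.78 to 3.86), and Il7r had a higher fold in cluster 1. A dividing-like cluster of 38 cells (6.32%, 4.51 to 8.58) had all 10 division markers and all 21 measured G2/M genes at 2-fold or higher. Its Mki67 level was 650 against 25.4 CPM (25.6-fold, 19.7 to 33.5), and it was led by Nusap1, Fbxo5, Kif11, Spc25 and Esco2.

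Among the clusters that took no name, cluster 1 was the largest, with 117 cells (19.5%, 16.4 to 22.9), and it held much of the interferon gamma transcript. Ifng, the main effector cytokine of CD8 T cells, was at 938 CPM against 128 (7.34-fold, 6.43 to 8.38), with 539 of the 930 Ifng UMIs of the pool. Il7r (2.95-fold, 2.42 to 3.58) and Tcf7 (2.13-fold, 1.65 to 2.74), genes of memory T cells, were higher in the same cluster. The CD8 T cell list itself had a median fold of 1.51 in cluster 1. Its other leading genes were Serpinb9b, whose UMIs came from 5 cells, Gm10827, Furin and Dgat1. In cluster 4 (70 cells), Slc17a9, Trim30c, Rbm43, Ung and Trim34a led at 2.75-fold to 3.25-fold, and 14 of 21 G2/M genes, 8 of 16 inhibitory receptor and exhaustion genes and 8 of 17 glycolysis genes were 2-fold or more lower. Low G2/M levels did not set cluster 4 apart, since 19 of 21 G2/M genes were 2-fold or more lower in cluster 1. The cells compared against include the dividing-like and exhausted-like clusters and cells of other types. The glycolysis list stood at 5784 CPM in cells passing the T cell rule and 7363 CPM in the pool. Low glycolysis in cluster 4 may thus partly mark T cells in general.

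**Figure D1:**
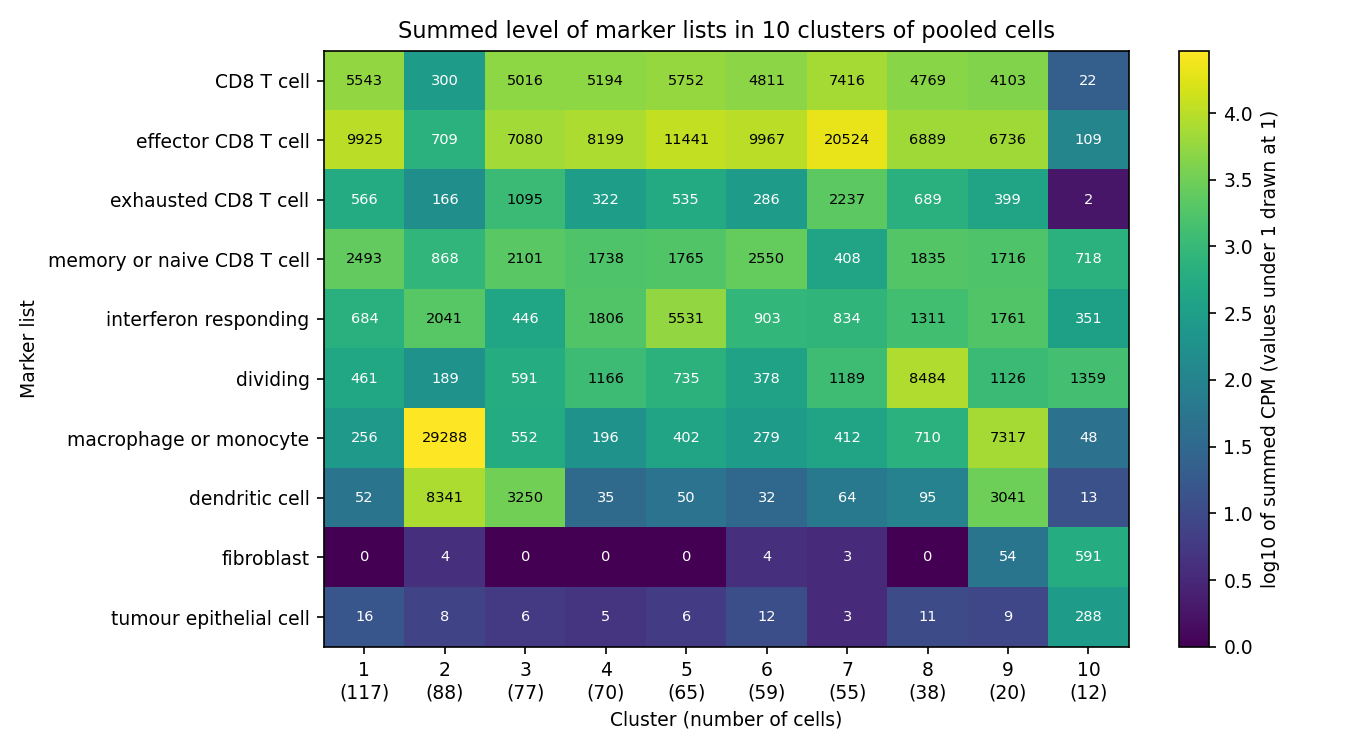
Summed CPM of 10 marker lists (rows) in the 10 clusters (columns, with cell numbers); colour is the log10 of the summed CPM printed in each cell. The macrophage or monocyte list stands at 29288 CPM in cluster 2 and 7317 in cluster 9, and the exhausted list at 2237 CPM in cluster 7 and 1095 in cluster 3.

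A macrophage-like cluster of 88 cells (14.6%, 11.9 to 17.7) had all 12 markers at 2-fold or higher. Lyz2, which encodes lysozyme, was at 8782 CPM against 62.7 (140-fold, 121 to 162) and C1qa, a complement component, at 1560 CPM (48.8-fold, 39.6 to 60.6). Inhba, Mmp8, Cxcl3, Ppbp and Mmp13 led it by fold, each with UMIs in 8 to 27 cells. The name was not reached under 5 of 9 alternatives. These include the setting with only cells passing the T cell rule, which 0 of the 88 cells passed, so the loss there was fixed in advance. Cluster 9 (20 cells, 3.33%) held both kinds of transcript: 85.0% of its cells had a T cell gene UMI, and its macrophage list stood at 7317 CPM. AY036118, Slc7a11, Gm42418, Ikbkap and Gas6 led it, with UMIs in 6, 1, 13, 6 and 3 of its cells. Cluster 3 (77 cells, 12.8%; 84.4% from barcode set 1) was a mixture. Of its cells 60 passed the T cell rule, and 10 of 16 inhibitory receptor and exhaustion genes and 4 of 7 exhaustion markers were 2-fold or more higher. Its leading genes Il12b, Cd200, Tbc1d4, Penk and Fscn1 came partly from few cells, with all 62 Il12b UMIs in 2 cells and its 194 Fscn1 UMIs in 5; it also held all 15 cells with at least 10% mitochondrial UMIs. Cluster 10 (12 cells) had a median of 56933 UMIs per cell and was led by Col3a1, Map1b, Prrx1, Krt8 and Serpinf1.

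At a common depth of 2000 UMIs, the effector gene Gzmb was found in more cells than any inhibitory receptor or memory gene in this set, while Prf1 and Gzma were found in few cells. Gzmb and Cd69, an early activation marker, were each found in 49.3% of the 515 cells (44.9 to 53.7). Cd8a was found in 40.2%, Cd3e in 31.5%, Il7r in 23.7%, Pdcd1 in 22.5% (19.0 to 26.4), Ifng in 21.4%, Tnfrsf9 in 20.4% and Lag3 in 19.8%. Lower shares were found for Ctla4 (17.1%), Tcf7 (16.3%), Top2a (15%), Mki67 (7.18%), Havcr2 (6.21%), Prf1 (5.83%), Gzma (3.11%), Tigit (1.75%) and Cd4 (0.388%). In macrophage-like cells, with a median of 4274.5 UMIs before thinning against 5007 in the pool, the thinned shares were 4.62% for Gzmb, 3.08% for Pdcd1, 4.62% for Cd8a and 1.54% for Tcf7. Il7r (32.3%) and Havcr2 (12.3%) were found in these cells at shares above those of the pool. Unthinned shares were higher, at 56.2% for Gzmb, 33.6% for Pdcd1 and 31.3% for Tcf7.

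T cells with a Pdcd1 UMI had higher summed levels of other inhibitory receptor genes and of cytotoxic genes, and lower summed levels of memory genes, than T cells without one. In 91 cells with and 251 without, the inhibitory receptor and exhaustion list was 1.74 times as high (1.55 to 1.95), with 7 of 10 measured members at least 1.5-fold higher and 0 lower; over 50 thinning draws the ratio had a median of 1.79 and ran from 1.5 to 2.16. Tox had a median ratio of 4.25 over the draws (2.40 to 8.55), Havcr2 5.61 (2.04 to 12.4), Lag3 2.02 (1.37 to 3.51) and Ctla4 1.90 (1.2 to 2.86). Part of these pooled ratios lies between the libraries, since 35.7% of T cells in barcode set 1 and 21.1% in barcode set 2 had a Pdcd1 UMI. Within the sets (first draw), the Tox interval lay above 1 in both (ratios of 4 and 6.22), Ctla4 was at 1.06 (an interval holding 1) and 2.61, and the intervals of Havcr2 (1.98 and 3.73) and Lag3 (1.40 and 1.38) held 1 in each. The cytotoxic effector list was 1.23 times as high (1.18 to 1.29; 1.17 to 1.5 over the draws), with 6 of 17 members higher and 1 lower, and with Gzmb at a median ratio of 2.11 (1.53 to 2.57), and 1.26 (0.98 to 1.60) and 1.90 (1.55 to 2.31) within the sets in the first draw. The memory and naive list was lower, at 0.66 (0.60 to 0.71; 0.62 to 0.79 over the draws), with 5 of 12 members lower and 2 higher, and Klf2, a regulator of lymphocyte trafficking, at a median of 0.46 (0.30 to 0.63). Each of these 3 lists lay on the same side of 1 in both barcode sets: 1.43 and 1.69 for the inhibitory list, 1.14 and 1.22 for the cytotoxic list, and 0.67 and 0.71 for the memory list. The G2/M list had a ratio of 2.22 (1.95 to 2.52) in the first draw, but this was the highest of the 50 draws, whose median was 1.52 and lowest 1.07. Glycolysis genes were at a median of 1.24 (1.12 to 1.37) and ribosomal protein genes at 0.85 (0.82 to 0.87) over the draws. Mitochondrially encoded genes were at 1.17 (1.12 to 1.22) in the first draw, with 1.23 and 0.92 in the sets, and above 1 in 46 of 50 draws. The NF-kB pathway list had a summed ratio of 1.01 (0.92 to 1.11), with 3 of 26 members higher and 5 lower, and ratios of 0.88 and 1.12 in the sets.

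T cells with an Ifng UMI, 89 against 253 without, had higher summed levels of early activation and inhibitory receptor genes. The early activation list had a ratio of 1.22 (1.15 to 1.29), with 6 of 19 members higher and 1 lower, a range of 1.13 to 1.32 over the draws, and 1.22 and 1.23 in the barcode sets. The inhibitory receptor and exhaustion list was at 1.38 (1.23 to 1.54; 1.15 to 1.55 over the draws), with 4 of 11 members higher and 1 lower and 1.67 and 1.29 in the sets, and glycolysis genes at 1.32 (1.23 to 1.41; 1.08 to 1.35 over the draws), with 1.13 (an interval holding 1) and 1.45. The exhaustion markers did not move together. Over the draws, Havcr2 had a median ratio of 2.09, Ctla4 1.42 and Lag3 1.38, each above 1 in 49 of 50. Pdcd1 (1.06), Cd160 (1.04) and Entpd1 (0.89) were above 1 in 33, 30 and 20 draws. Tox was lower, at 0.69 (0.32 to 1.14), above 1 in 2 of 50 draws. The cytotoxic list had a ratio of 1.18 (1.13 to 1.23) in the pool, but 1.60 in barcode set 1 and 0.97 in barcode set 2 (first draw, with 28 and 61 Ifng cells). The memory and naive list was at 0.95 (0.88 to 1.02), an interval that holds 1. The G2/M list was again at its highest in the first draw, at 1.92; over the draws its median was 1.24 and it lay above 1 in 43 of 50. The S phase list went the other way, at 0.89 (0.74 to 1.06), above 1 in 6 of 50 draws, with 0.55 (0.37 to 0.78) in barcode set 1 and 1.08 (0.88 to 1.33) in barcode set 2. The NF-kB pathway list was at 1.13 (1.03 to 1.23; 1.09 to 1.35 over the draws), but at 0.87 in barcode set 1 and 1.29 in barcode set 2. Ribosome biogenesis genes were lower, at 0.82 (0.75 to 0.89; 0.77 to 0.94 over the draws).

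T cells with a UMI of Tcf7, which encodes the transcription factor TCF1 of memory T cells, had lower summed levels of cytotoxic genes and slightly higher ones of other memory genes. In 68 cells with and 274 without, the cytotoxic list was at 0.72 (0.68 to 0.76; 0.63 to 0.88 over the draws), with 6 of 17 members lower and 1 higher, and the memory and naive list at 1.17 (1.08 to 1.27; 1.04 to 1.32 over the draws), with 5 of 11 higher and 0 lower. Interferon-stimulated genes were at 0.78 (0.73 to 0.84; 0.66 to 0.97 over the draws), with 0.79 and 0.78 in the sets, and the NF-kB pathway list at 1.15 (1.04 to 1.26; 1.02 to 1.35 over the draws), with 1.16 (an interval holding 1) and 1.14. Gzmb had a median ratio of 0.46 over the draws (0.30 to 0.71). Mitochondrially encoded genes were lower too, at 0.82 (0.78 to 0.86; 0.82 to 0.99 over the draws), with 0.81 and 0.84 in the sets. In the first draw, with 25 and 43 Tcf7 cells in the sets, the cytotoxic ratio was 0.55 in barcode set 1 and 0.86 in barcode set 2. The memory ratio was 1.37 and 1.09, where the second interval (0.99 to 1.2) held 1. The inhibitory list was at 0.85 (0.74 to 0.98) in the pool, at 0.72 in barcode set 1 and at 1.07 in barcode set 2, where its interval (0.87 to 1.31) held 1.

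**Figure D2:**
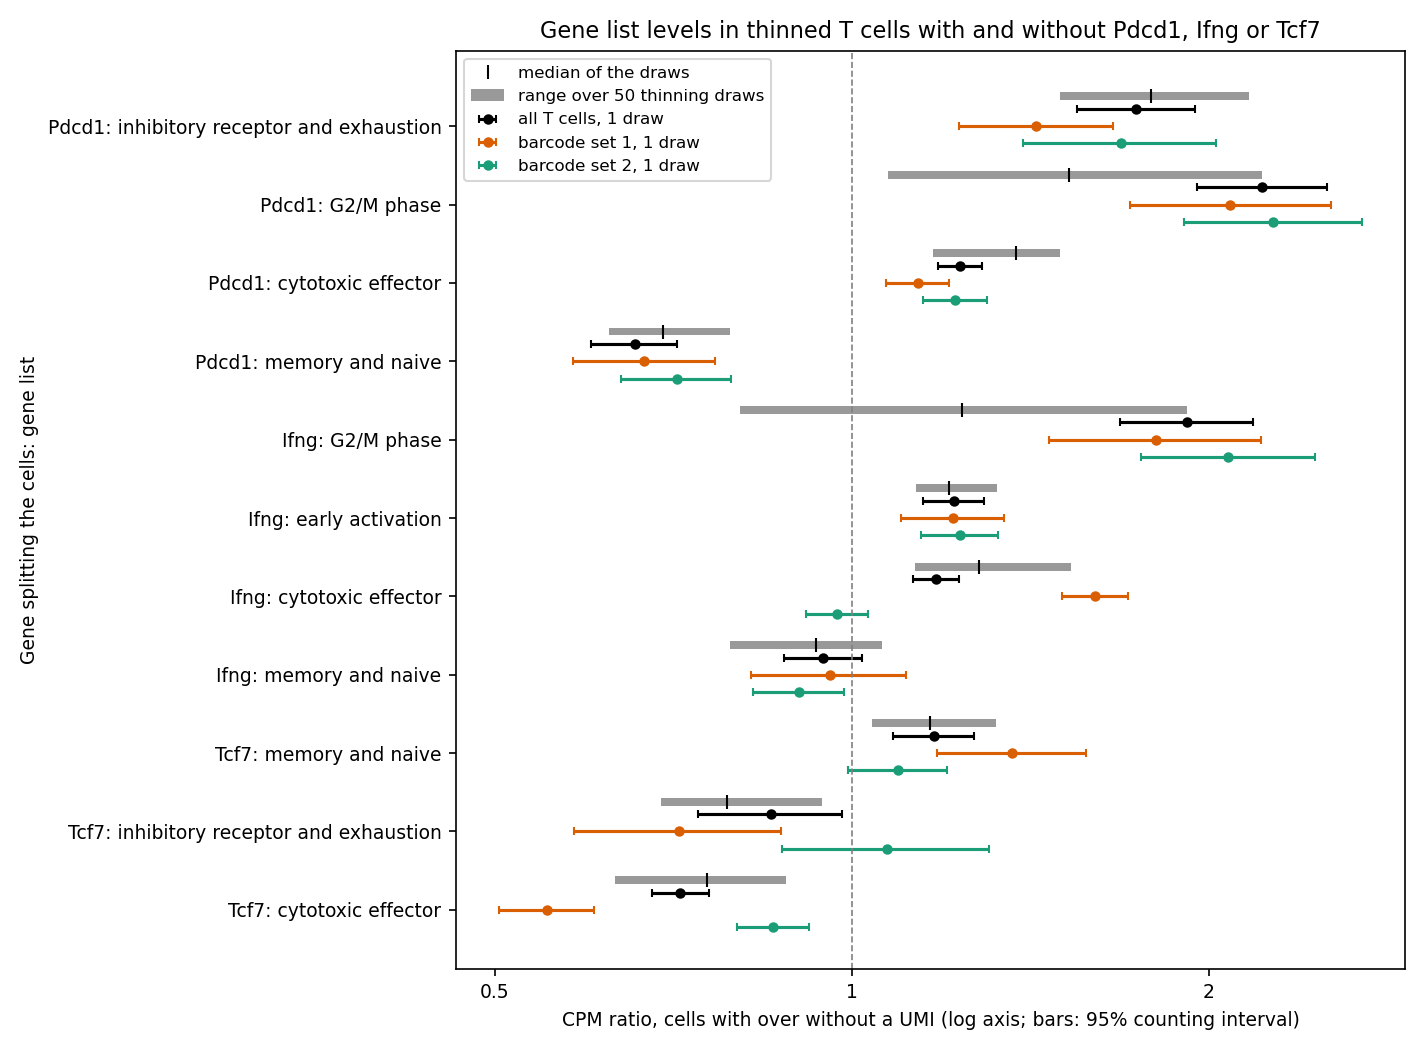
CPM ratio of gene lists (log axis) between thinned T cells with and without a UMI of Pdcd1, Ifng or Tcf7; points with bars are 1 draw with 95% counting intervals for all cells (black), barcode set 1 (orange) and barcode set 2 (green), and grey bars span 50 draws with their median as a tick. The Pdcd1 inhibitory list lies between 1.5 and 2.16 over the draws, and the Ifng G2/M list spans 1, from 0.80 to 1.92.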

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

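The alternatives for the split by a gene, for the naming rule and, for clusters, for thinning, doublets, the mitochondrial filter and the T cell rule were added after the data were seen. Of the values that answer the main questions, 107 stayed within the counting interval, 38 moved beyond it and 2 moved beyond it with a change of sign; 1 value changed sign within it (memory list with Ifng, 0.011 with a second draw); of 19 thinned shares, 17 moved unthinned. The ratios between the groups, with median-of-ratios scaling, the choice of minimum counts and the ranking of genes by ratio, were not run because no barcode could be mapped to a sample. The cause of the moves below was not tested unless stated.

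The T cell rule gave 78.1% thinned and 85.5% with no limit on other lists. The exhausted-like share was 22% at resolution 0.4, 14.8% with 10 components and 18.4% with at least 500 genes and under 10% mitochondrial UMIs. The interferon-responding-like share was 17.6% at resolution 1.2, 18.8% with at least 500 genes, 21.6% thinned and 21.1% with the mitochondrial filter too. The memory or naive-like share was 41.3% at resolution 0.4, 17.1% with 10 components, 17.4% with at least 500 genes and 25% with both filters; the name was not reached in 4 of 9 alternatives. The macrophage-like share was 7.82% at resolution 1.2, 6.16% with 10 components and 11.1% without cell cycle and ribosomal protein genes. At resolution 1.2 only 1 of its subclusters took the name, and 5 of 9 alternatives gave none. Among these is the setting with only cells passing the T cell rule, where the name could not be reached. The dividing-like share (5.88% to 7.59%) and the Dhx37 level (4.85 to 8.23 CPM) stayed within their intervals.

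The naming rule was set after the clusters were seen, in 4 versions. With no own marker needed, the exhausted-like share was 22% (cluster 3 added) and the macrophage-like share 18% (cluster 9 added); with an own marker among 20 leading genes the latter was 18% too. In both, T cell gene CPM in macrophage-like cells was 17.7% of that in T cells, against 5.23% in the version kept, and 66.7% of the cells had no T cell gene UMI, against 78.4%. Naming macrophages by level left the main share at 14.6% and gave 14.6% to 19.5% over 8 alternatives; the kept rule gave values in 4.

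For the splits (log2), a second thinning draw gave 0.38 for the cytotoxic list with Pdcd1, -0.19 with Tcf7 and 0.32 with Ifng, and 0.51 and 0.53 for the G2/M list with Pdcd1 and Ifng. Unthinned values were 0.44 (Pdcd1), -0.63 (Tcf7) and 0.30 (Ifng) for the cytotoxic list, -0.51 for the inhibitory list with Tcf7 and 0.72 for G2/M with Pdcd1. Over all cells of clusters with T cell genes in over 90% of cells, Pdcd1 gave 0.38 for the cytotoxic and 0.96 for the G2/M list. In barcode set 1 alone, the inhibitory and cytotoxic lists with Pdcd1 were at 0.52 and 0.18, the memory, cytotoxic and inhibitory lists with Tcf7 at 0.45, -0.85 and -0.48, and the cytotoxic list with Ifng at 0.68. In barcode set 2 alone, the memory and cytotoxic lists with Tcf7 were at 0.13 and -0.22, the inhibitory list with Tcf7 turned to 0.10 and the cytotoxic list with Ifng to -0.042.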

Other observations

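All tests here were chosen after the patterns had been seen. At resolution 1.2 the 88 macrophage-like cells fell into 47 and 41 cells with different genes and depths (medians of 2826 and 7073 UMIs); these genes were chosen by fold after the split. In the 47 cells, Ccl8 was at 5066 against 130 CPM (38.9-fold, 28.0 to 55.6), Folr2 was 12.3-fold and Apoe 4-fold higher, and Igf1 was at least 27.0-fold higher. In the 41 cells, Il1b, an inflammatory cytokine, was at 2374 against 46.7 CPM (50.9-fold, 26.6 to 112). The MHC class II gene H2-Ab1 was 60.7-fold higher (31.8 to 133). Ccr2, a monocyte chemokine receptor, was 54.3-fold higher, but against 1 UMI in the other cells (9.48 to 2172). Within cluster 3, 5 cells with at least 5 Fscn1 UMIs had a median of 23 Ccr7 UMIs, 248 UMIs of 4 antigen presentation genes (Cd74, H2-Aa, H2-Ab1 and H2-Eb1) and 0 of the T cell genes, while the other cells of the cluster had a median of 0 UMIs of the antigen presentation genes and 15 of the T cell genes.

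The barcode sets, which are unassigned libraries, filled some clusters differently, and nothing here says which treatment either had. In barcode set 1 the shares were 6.67% (3.78 to 10.8) in cluster 1, 28.9% (23.1 to 35.3) in cluster 3, 5.33% (2.79 to 9.13) in cluster 4 and 22.7% (17.4 to 28.7) in the exhausted-like cluster; in barcode set 2 they were 27.1% (22.7 to 31.9), 3.19% (1.66 to 5.51), 15.4% (11.9 to 19.5) and 1.06% (0.291 to 2.70). Intervals overlapped for the interferon-responding-like (7.11% and 13.0%), macrophage-like (11.1% and 16.8%), memory or naive-like (8.44% and 10.6%) and dividing-like (6.22% and 6.38%) clusters, and for cluster 9 (2.22% and 3.99%) and cluster 10 (1.33% and 2.39%). Overlapping intervals do not show that the sets were alike. Among cells passing the T cell rule, the interferon responding list was at 953 CPM (884 to 1026) in barcode set 1 and 1797.5 CPM (1722 to 1875) in barcode set 2. The memory or naive list was at 1539 CPM (1451 to 1631) and 2132 CPM (2050 to 2217), and the dividing list at 1653 CPM (1561 to 1748) and 1487 CPM (1418 to 1558). In the same cells, Tox was at 159 CPM (132 to 191) in barcode set 1 and 24.5 CPM (16.4 to 35.1) in barcode set 2, and Il7r at 85.1 CPM (65.4 to 109) and 198 CPM (174 to 225). Dhx37 had 8 UMIs in barcode set 1 (6.33 CPM, 2.73 to 12.5) and 13 in barcode set 2 (5.49 CPM, 2.92 to 9.38).

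The exhausted-like cluster came mostly from barcode set 1, with 51 of 55 cells (92.7%, 82.4 to 98.0), although that set gave 37.4% of all cells. Depth is argued against as a cause by 93.5% of 46 cells after thinning and new clustering, and doublets or cells of other types by 85.7% of 42 cells after clustering only cells that passed the T cell rule. Damaged cells are argued against for these 55 cells alone, since 0 of them (0%, up to 6.49) had under 500 genes or at least 10% mitochondrial UMIs. That 0 depends partly on the clustering, which put all 15 cells with at least 10% mitochondrial UMIs into cluster 3. The first naming version called cluster 3 exhausted-like too. A first test, which filtered on these limits and clustered again, was dropped because the limits removed none of the 55 cells. A difference between library preparations may account for it, and with 1 library behind each set that cannot be told apart from an effect of treatment or of the mouse, which stays untested.

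Macrophage-like cells were present although the sort was for CD8 T cells. Doublets with a T cell are argued against by their T cell gene CPM, 5.23% of that in cells passing the T cell rule. Free macrophage RNA in T cell droplets is argued against by the 78.4% (68.4 to 86.5) of these cells with no T cell gene UMI. Both values cover cluster 2 alone; with cluster 9 they are 17.7% and 66.7%, and the 20 cells of cluster 9, with T cell and macrophage transcripts together, may be doublets, which stays open: 3 of them were predicted doublets, against 23 cells in the pool, and their median depth of 4294.5 UMIs was below that of the pool. No biological explanation was tested.

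The 12 cells of cluster 10 held 14.9% of all UMIs, and 8 of them were the only cells of the pool above 40000 UMIs. Doublets with a T cell are argued against by a T cell gene CPM of 0.475% of that in T cells, where a T cell in so large a droplet would give about 8.58%. Whether they could be tumour cells rather than fibroblasts cannot be told apart, because only 1 tumour epithelial marker (Krt8) and 2 fibroblast markers (Col3a1 and Sparc) reached 50 UMIs.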
